A study of Mus musculus with 7 samples.

How the data were processed

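ATAC-seq libraries came from sorted splenic Tfh cells of 7 B6/Sle1.Yaa samples, 4 from mice given anti-IFNAR1 and 3 from mice given anti-rat IgG. The treatment labels write the antibody's target as IFNA1 and the series title as IFNAR1, and anti-IFNAR1 is used here. Groups were taken from the treatment label of each sample. The labels do not say whether each sample came from 1 mouse or several.

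Per the submitters' processing notes, BWA 0.7.9a, MACS2 2.1.0.20150420, DiffBind 2.0.7, DESeq2 and bedtools were used with genome build mm10, and the notes as used here give no role or order. How the transposase cut sites were shifted, and how duplicates were treated, is not given in the sources used here. The authors' deposited table was a peak list in the layout of MACS2 with the gene, transcript and section nearest to each peak. Its peak names state a comparison of IFN against Ig treatment. The direction, with anti-IFNAR1 as the treated side and control IgG as the background side, was read from these names and the sample titles. Which libraries entered each side is not stated, and pooling of each group was assumed.

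Per the file headers, the signal is the pileup, the number of overlapping fragments at the summit, scaled by the authors' caller. The fold enrichment, a ratio over the local background, was also deposited by the authors. The headers of 2 further deposited columns were damaged. Their values were read as −log10 p and −log10 q, and for the first of them a Poisson −log10 p recomputed from pileup and background differed by at most 0.000125 from the deposited value. No p-value, q-value, pileup or fold was fitted anew from samples, since no column carries a sample.

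The pileup of every peak was a whole multiple of 0.283 within rounding (tolerance 0.005), so each value could be turned back into fragments. The deeper anti-IFNAR1 side had been scaled down by that factor, a depth ratio of 3.54. The control background followed from the fold, with the caller's pseudocount of 1 on both sides. It came from the site itself for 2379 peaks, from a 1 kb window for 2832, from a 10 kb window for 540 and from the genome rate for 644, with a fragment length of 236 bp. If the caller's built-in mouse genome size was used, the control side held about 1050000 fragments and the anti-IFNAR1 side about 3700000. Depth per sample is unknown. The caller treats the background as known without error, which makes its p-values small where few control fragments were counted. Therefore a one-sided exact conditional binomial test was added that counts noise on both sides, once with the window the caller used and once at the site alone. The added test uses unscaled anti-IFNAR1 fragments. The caller's p-values use the scaled-down coverage, which makes them larger. For the 644 peaks at the genome rate, the test with the caller's window was a Poisson test without control noise. Where the background came from a wider window, the control fragments at the site are unknown. They were set to the most that the background allows, so the number of peaks kept at the site is a minimum.

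The design fixed before the data were examined assumed values per sample for the fits of differential accessibility. Since the file held only the authors' statistics, their list at q of 0.05 was used as it stands. Every listed peak is past that threshold in 1 direction, so the planned test of the share of peaks past the threshold was void, and adjustment over the list alone would have been too. Gene lists were instead tested per gene. For each of 13 lists fixed before the data were examined, the share of protein-coding members with at least 1 listed peak was compared with the other protein-coding genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the lists. The background was all 21900 protein-coding genes of RefSeq (GRCm38.p6, the same build), of which 4610 had a listed peak, and it includes genes that are closed in T cells. For that reason each list was also set against the housekeeping list, a comparison chosen after the data were seen. All 340 list entries matched a RefSeq symbol or synonym and named 317 genes, 23 of them in more than 1 list. Gene names of 5467 peaks matched RefSeq, and 11 matches that lay elsewhere were dropped. Gene positions of Il21 and Ifng are from RefSeq, and peak positions are as the file gives them.

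The median fold of each list with at least 5 peaks was set against 10000 random peak lists matched on deciles of pileup, which compares listed peaks with each other only. The median fold of each section was tested against the other peaks by permutation. Shares have Wilson 95% intervals and ratios exact intervals, and all of them cover counting error only. PCR copies of a fragment are not independent molecules. The TSS section of the file reaches from 997 bp upstream to 99 bp downstream.

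Genes and peaks are named by a rule fixed before the data were examined. It takes every peak at Il21 and Ifng, the 10 peaks with the smallest adjusted p, up to 4 peaks with the smallest adjusted p in each list, and Ifnar1, Ifnar2 and Tlr7. Some genes that the rule takes are not reported here. Further list members are named by their count of peaks alone, and they and Ddx3y were chosen after their values were seen. Alternatives were a q of 0.01, a pileup of at least 20, a fold of at least 1.5, promoters within 1 kb, promoter peaks alone, 1 value per gene, assignment by gene span with 5 kb flanks, and both exact tests. The 14 planned sequence motifs were not searched, since no genome sequence was used here.

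The scripts were tested on 6395 simulated peaks drawn with the depths and backgrounds of the list. Decoding was checked apart from these, on the list's own decoded fragments and backgrounds turned back into pileup and fold. It returned 100% of the fragments. That outcome was largely fixed by the construction and does not test the decoding of the deposited values. With control fragments drawn and counted at every site, the exact test called 0% of unchanged peaks, 0% of peaks with a 2-fold difference, 21.0% at 5-fold and 55.5% at 10-fold. Wider windows, the genome rate and control fragments set to the most that the background allows were not simulated. These rates therefore do not describe the tests of peaks without a background counted at the site. Random gene lists gave a Fisher's exact p under 0.05 in 2.6% of draws. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.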

Results

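Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in T follicular helper (Tfh) cells sorted from the spleens of 5-month-old B6/Sle1.Yaa mice. This strain is prone to a lupus-like autoimmune disease, and Tfh cells are the CD4 T cells that help B cells in germinal centres. The sort took CD4 and CD44 positive, GITR negative cells with low PSGL-1 and high CXCR5 and PD-1. Mice had received an antibody against IFNAR1, a chain of the receptor for type I interferon, or control anti-rat IgG, 2 times a week for 4 weeks. There were 4 anti-IFNAR1 samples and 3 control IgG samples. The series title names the Il21 and Ifng loci, which encode the cytokines IL-21 and interferon gamma, as the question behind the comparison.

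The data were 1 list of 6395 peaks on 21 chromosomes (mm10), each with higher coverage on the anti-IFNAR1 side than the control IgG background. The coverage, fold and −log10 q of each peak are the authors' own values from their deposited table. Values of single mice were not analysed here, so no value below carries a spread between mice. Peaks that were higher in control IgG mice were not analysed here either. The anti-IFNAR1 side held 3.54 times as many fragments as the control side, where libraries of equal depth would give 1.33.

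The listed peaks lay mainly at gene starts. The file placed 4632 of 6395 peaks at a transcription start site (TSS), which was 72.4% (Wilson 95% interval 71.3 to 73.5). Intergenic sites held 702 peaks (10.98%), introns 448 (7.01%), 5′ UTR exons 232 (3.63%) and coding exons 224 (3.50%). A further 127 peaks lay at transcription termination sites and 30 in 3′ UTR exons. The median fold over the control background was 4.76 at TSS peaks, 4.71 at intergenic peaks and 4.62 at intron peaks, against 4.74 over the list. No section's median fold differed from the other peaks after Benjamini-Hochberg adjustment over the 7 sections (two-sided permutation test, lowest adjusted p = 0.143 for 5′ UTR exons).

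Most of these sites were also covered, at the peak or around it, on the control IgG side. The median background on the control side was 1.49 fragments per site, and 4374 peaks (68.4%) had a background of at least 1 control fragment. The caller takes the largest of the site, window and genome values, so no background lies below the genome rate of 0.132. Sites simulated at that rate had a median background of 0.189. The 5751 peaks (89.9%) above the rate, and the median of 11.3 times the rate, therefore overstate the coverage on the control side. The background was counted at the site itself for 2379 peaks (37.2%). A further 2021 peaks had a background below 1 fragment and so 0 control fragments at the site. For the remaining peaks the background came from a window, and the control fragments at the site are unknown. A median of 41 anti-IFNAR1 fragments stood at each summit, with a range of 11 to 512. When the counting noise of the control fragments entered an exact test at the site itself, 1335 of the 6395 peaks stayed at or below the largest p of the list, 6.90e-05. Unknown control fragments at the site were set to the most that the background allows, so 1335 is a minimum.

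**Figure D1:**
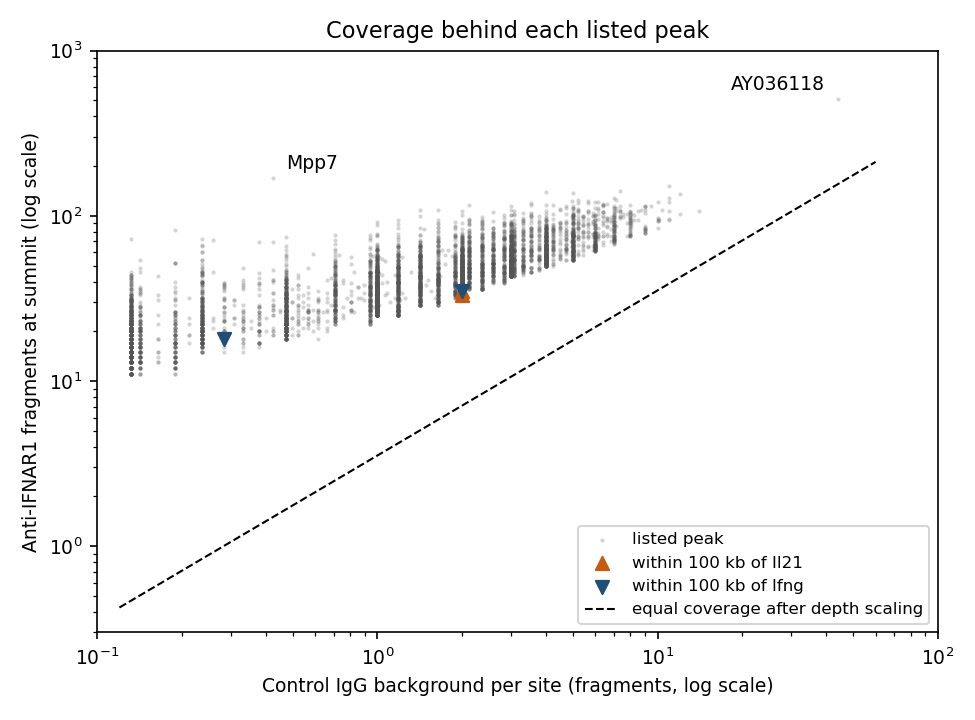
Anti-IFNAR1 fragments at the summit (vertical, log scale) against the control IgG background per site in fragments (horizontal, log scale) for each of the 6395 listed peaks; the dashed line marks equal coverage after scaling for the 3.54 times greater depth. Mpp7 stands apart with 170 fragments over a background of 0.425, and peaks within 100 kb of Il21 and Ifng (triangles) have 18 to 35 fragments.

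At Il21, the cytokine gene that defines Tfh help to B cells, 1 listed peak lay at the 5′ end of the gene. It spanned chromosome 3 from 37232635 to 37232886, and the Il21 gene runs from 37222759 to 37232636 on the same build. The file assigned this peak to the TSS of the neighbouring transcript Gm43822. It held 35 anti-IFNAR1 fragments and 2 control fragments, with a fold of 3.63 and a q of 0.0352 in the authors' deposited table. A further peak within 100 kb of Il21 lay at the TSS of Cetn4, a centrin gene, from 37312737 to 37313713, with 33 against 2 fragments and a fold of 3.44.

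At Ifng, the gene for interferon gamma, 2 peaks were listed. The peak in intron 1 of Ifng spanned chromosome 10 from 118441873 to 118442379, 826 bp from the TSS, with 18 anti-IFNAR1 fragments over a background of 0.283, a fold of 4.74 and a q of 0.000884 in the authors' deposited table. An intergenic peak from 118419114 to 118419355 had its summit 21.9 kb upstream of Ifng, with 35 against 2 fragments and a fold of 3.63. The Il21, Cetn4 and intergenic Ifng peaks shared rank 6173 of the 6395 by q, and the Ifng intron peak had rank 3975.

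Scaled for depth, coverage at the Il21 promoter peak was 4.95 times the control side (exact 95% interval 1.27 to 42.5), and the same values held for the intergenic Ifng peak. The one-sided exact p, with the noise of the control fragments included, was 0.00646 for each of these peaks and 0.00960 for the Cetn4 peak, above the largest p of the list. That p needs 39 fragments at a site even with 0 control fragments, so these peaks, with 33 to 35, could not have reached it. The Ifng intron peak reached it against the 12 control fragments in the surrounding 10 kb (exact p = 3.20e-13) and with 18 fragments could not have reached it against the site alone, where the control side had 0 (exact p = 0.0113). These intervals cover the counting error of pooled fragments and no spread between mice. The peaks were listed because their summit coverage was high over the control, and the same counts enter here. Ratios and exact p-values are therefore tilted towards a gain, and the interval cannot decide against equal coverage.

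**Figure D2:**
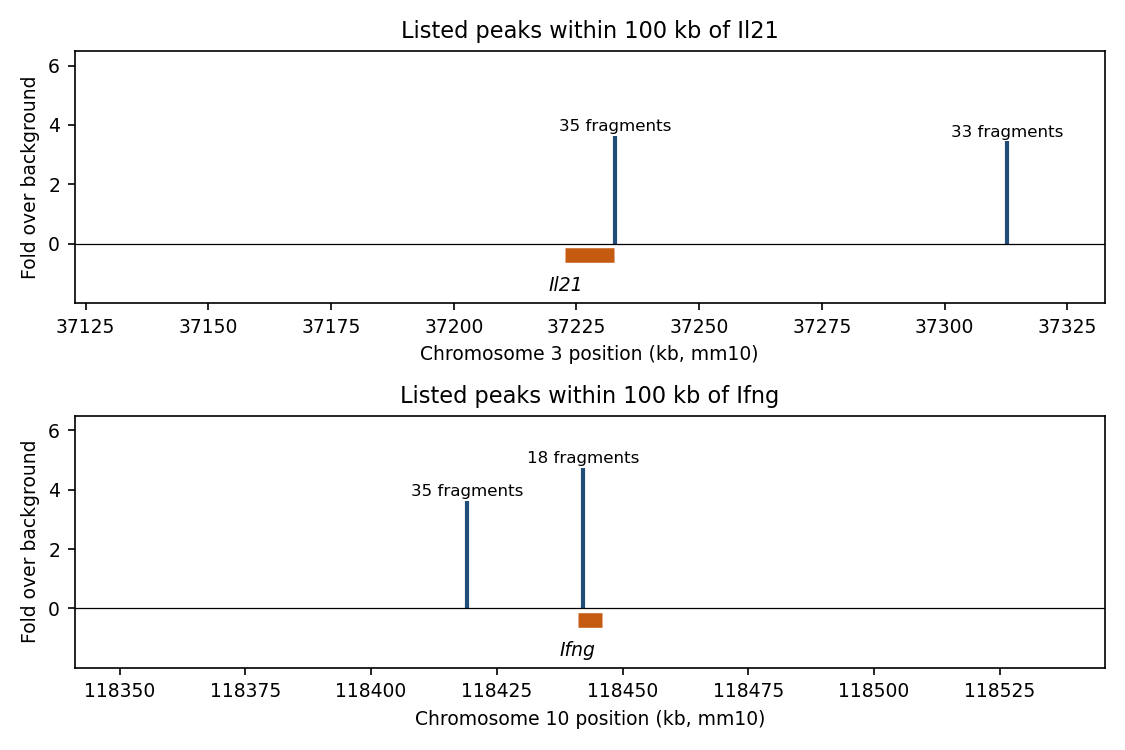
Fold over the control IgG background (vertical) of the 4 listed peaks within 100 kb of Il21 on chromosome 3 and Ifng on chromosome 10 (horizontal, position in kb, mm10); orange bars mark the genes and numbers give the anti-IFNAR1 fragments. The Il21 promoter peak had a fold of 3.63 and the Ifng intron peak 4.74.

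Genes of the Tfh programme were listed far more often than other genes. Of 35 Tfh genes, 25 (71.4%) had at least 1 listed peak, against 21.0% of other protein-coding genes (two-sided Fisher's exact test, adjusted p = 2.89e-09 over 13 lists). They included Bcl6, the master transcription factor of Tfh cells, with 2 peaks, Pdcd1, which encodes PD-1, with 2, and Nfatc1 with 4. The strongest by q were Id3, an inhibitor of E proteins, with a fold of 8.08, Tnfsf8, the CD30 ligand gene, with 8.55, Maf, a driver of IL-21 expression, with 4.82, and Tcf7, which encodes the transcription factor TCF-1, with 6.71. Il21 itself, Cxcr5, Icos, Il4 and S1pr2 were among the 10 without an assigned peak. The peak at the 5′ end of Il21 was the one assigned to Gm43822.

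Of the AP-1 and NF-κB genes, 18 of 23 (78.3%, adjusted p = 4.64e-08) were listed. The inhibitor gene Nfkbid reached a fold of 11.1, Nfkb2 9.42, Mafk 9.09 and the AP-1 gene Fosl2 6.31 in the authors' deposited table. Of the cytokine receptor and JAK-STAT genes, 18 of 31 (58.1%, adjusted p = 3.26e-05) were listed, led by Il10rb, a shared receptor chain, with a fold of 8.86, Stat3 with 5.11 and Stat6 with 6.20. Activation and exhaustion genes had 15 of 25 listed (60%, adjusted p = 8.32e-05), among them Cblb, a ubiquitin ligase that restrains T cell activation, with a fold of 5.85, and the inhibitory receptor genes Cd5 with 6.81 and Lag3 with 5.23. The Cblb peak lay in an intron 29016 bp from the TSS, and a further Cblb peak had a fold of 3.13. The immediate early gene Egr1 had a fold of 3.52. The Lag3 peak missed the largest p of the list in both exact tests (p = 0.000189).

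Housekeeping genes were also listed more often than other genes. Of 16 such genes, 10 (62.5%, Wilson 95% interval 38.6 to 81.5, adjusted p = 0.000996) had a peak, with folds of 4.07 at Actb, 5.09 at B2m, 3.92 at Eef1a1 and 3.28 at Ppia. Set against the housekeeping genes, no difference passed the test for Tfh genes (Fisher's exact test, adjusted p = 0.641 over 12 comparisons), AP-1 and NF-κB genes (0.419), cytokine receptor and JAK-STAT genes (1.00) or activation and exhaustion genes (1.00).

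Type I interferon-stimulated genes were not listed more often than other genes, at 16 of 67 (23.9% against 21.0%, adjusted p = 0.622). This share was below that of housekeeping genes (adjusted p = 0.0167). Peaks lower on the anti-IFNAR1 side were not analysed, so a loss of accessibility at these genes could not be seen. The listed members included Parp9, with a fold of 7.07, Sp100, a nuclear body gene, with 6.07 and Nmi with 5.52. Irf7 and Irf9, regulators of the interferon response, had a peak each, while Isg15, Mx1, Ifit1, Ifit3, Usp18, Rsad2 and Bst2 had none assigned.

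Th1 and cytotoxic effector genes were listed in 9 of 36 cases (25%, adjusted p = 0.622), below the housekeeping share (adjusted p = 0.0332). Beside Ifng these were Bhlhe40, a regulator of cytokine production, with a fold of 6.56, Zeb2 with 5.63 and Stat4, the transcription factor of IL-12 signalling, with 4.66. The others were Cx3cr1, Hlx, Id2, Il2ra and Il2rb. The Cx3cr1 peak, with a fold of 4.18, was placed in a 3′ UTR exon, 84511 bp from the Cx3cr1 TSS. Tbx21, which encodes the Th1 regulator T-bet, and Cxcr3, Gzmb and Prf1 had no assigned peak. Naive and memory T cell genes had 8 of 20 listed (40%, adjusted p = 0.0951), led by the survival gene Bcl2 with a fold of 8.42, Foxp1 with 7.40 and Foxo1 with 6.47. Th2 and Th17 genes had 5 of 18 (27.8%, adjusted p = 0.622), with Rora at 5.53, Il17re at 5.88 and Ahr at 4.57. Regulatory T cell genes had 5 of 19 (26.3%, adjusted p = 0.622), with Areg at 6.63, Entpd1 at 4.72 and Nrp1 at 3.50, and no peak assigned to Foxp3 or Ikzf2. The Il17re peak lay at a transcription termination site, 10419 bp from the TSS, and the Entpd1 peak in a 5′ UTR exon 19546 bp from the TSS. The Ahr peak and the Nrp1 TSS peak missed the largest p of the list in both exact tests (p = 0.000834 and 0.00264). When a peak within 5 kb of the gene counted, the regulatory T cell share was 52.6% against 29.1% of other genes (adjusted p = 0.0846), and with promoter peaks alone 15.8%.

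None of 16 B cell markers had an assigned peak, Cd79a, Ms4a1 and Pax5 included, which was below the housekeeping share (adjusted p = 0.00298) and did not pass the test against other genes (adjusted p = 0.0701). None of 12 CD8 T and NK cell markers had one (adjusted p = 0.00530 against housekeeping genes and 0.135 against other genes). Of 20 myeloid markers, 3 were listed, a share that did not pass the test against other genes (15.0%, adjusted p = 0.783) and lay below the housekeeping share (adjusted p = 0.0167). These were Cebpa, a myeloid transcription factor gene, with a fold of 5.41, Irf8 with 5.88 and Cd14 with 4.13. The Cd14 peak lay at a transcription termination site, 519 bp from the TSS. When a peak within 5 kb of the gene counted, the shares were 35% for myeloid markers, 6.25% for B cell markers and 8.33% for CD8 T and NK cell markers, against 29.1% of other genes, and none passed the test.

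Of the list peaks given here with a fold, those of Tcf7, Sp100, Nmi, Cd5, Zeb2, Stat4, Foxp1, Il17re, Areg, Entpd1, Irf8 and Cd14 were kept in the exact test with the caller's window and missed the largest p of the list at the site alone. For Zeb2, Il17re, Areg, Irf8 and Cd14 the background was the genome rate, and the test with the caller's window held no control noise. Other than Nmi, Stat4 and Cd5, these peaks had fewer than the 39 fragments that the test at the site needs. For Nmi, Stat4 and Cd5 the control fragments at the site are unknown and were set to the most that the background allows. With 0 control fragments there, their 39, 48 and 45 fragments would have reached the largest p of the list.

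With 1 fold per gene, no list's median fold stood apart from random lists of listed peaks matched on coverage (lowest adjusted p = 0.330). When every peak was counted, several of 1 gene included, the median of the 38 Tfh gene peaks was 4.10 and that of the 8 regulatory T cell peaks 3.92, both below the random lists (permutation against 10000 random lists, adjusted p = 0.0420 and 0.0480). With 1 value per gene these became 4.29 and 4.13 (adjusted p = 0.391 for each), while promoter peaks alone kept the Tfh median below the random lists (4.04, adjusted p = 0.0416). The other 8 lists with at least 5 peaks did not pass either way.

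**Figure D3:**
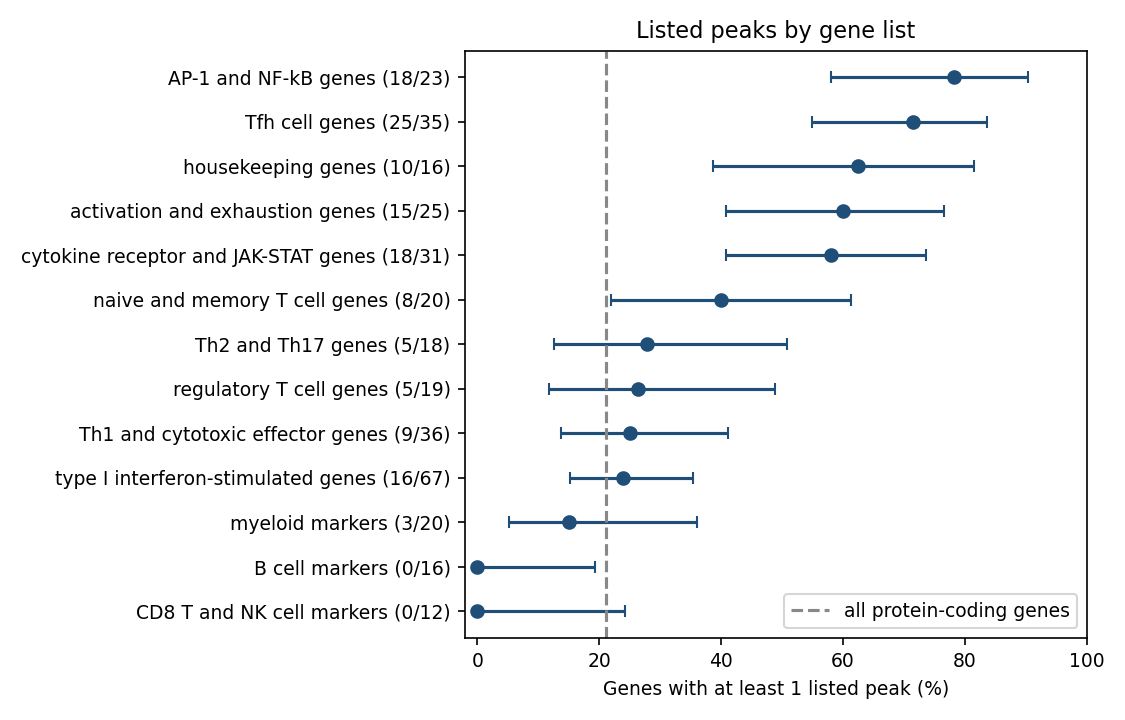
Share of genes with at least 1 listed peak (horizontal, percent) for each of the 13 gene lists; points are the shares, bars are Wilson 95% intervals that cover counting error only, and the dashed line is the share over all 21900 protein-coding genes, 21.1%. AP-1 and NF-κB genes (78.3%), Tfh genes (71.4%) and housekeeping genes (62.5%) lie to the right of that line, and B cell and CD8 T and NK cell markers lie at 0.

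The peak with the smallest q lay in a 5′ UTR exon of Mpp7, a scaffold protein gene, on chromosome 18 from 7609195 to 7609868. It held 170 anti-IFNAR1 fragments over a background of 0.425, a fold of 34.4, whereas the peak at the TSS of Mpp7 had a fold of 3.50. Next came TSS peaks of Kdm3b, a histone demethylase gene (chromosome 18, 34776798 to 34777632), with a fold of 20.3, Dtx4, a ubiquitin ligase gene (chromosome 19, 12501147 to 12502246), with 18.9, and Bfar, an apoptosis regulator gene (chromosome 16, 13671766 to 13672813), with 17.3. The RNA exosome gene Exosc8 (chromosome 3, 54734789 to 54735855) had a fold of 16.7, the cholesterol synthesis gene Dhcr7 (chromosome 7, 143829556 to 143830456) 13.2, the ribosomal protein gene Rpl7 (chromosome 1, 16104398 to 16106244) 15.9 and Fam208a (chromosome 14, 27428708 to 27429611) 13.5, all at the TSS. An intergenic peak on chromosome 2, from 34802038 to 34803094, had a fold of 16.1. These values stand in the authors' deposited table, and each of these peaks also passed the exact test at the site.

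AY036118, a transcript on chromosome 17, had the fifth smallest q. Its peak, from 39843132 to 39848712, was the widest of the list at 5580 bp, with 512 anti-IFNAR1 fragments over a control background of 43.9 and a fold of 3.25. Both sides were deeply covered there, and whether reads at this site are shared with other copies of the sequence was not tested.

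No peak was assigned to Ifnar1, which encodes the antibody's target, to its partner chain gene Ifnar2, or to Tlr7, the innate RNA sensor gene on the Yaa translocation. The nearest listed peak to Ifnar2, within 5 kb, was the Il10rb TSS peak. The list held 152 peaks on chromosome X and 1 on chromosome Y, at the TSS of Ddx3y.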

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

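The exact tests, the stricter q for loci, sections and gene lists, the pileup filter for sections and the assignment by gene span were chosen after the data were seen, and the other alternatives before. The list fell from 6395 peaks to 5270 at a q of 0.01 and to 797 with a pileup of at least 20. It fell to 4392 in the exact test with the caller's window and to at least 1335 in the exact test at the site. The 4392 include the 644 peaks at the genome rate, whose test held no control noise. All 6395 had a fold of at least 1.5. Of the 4 peaks at the Il21 and Ifng loci, 1 was left when assigned peaks alone were counted, 1 at a q of 0.01, 1 in the exact test with the caller's window and 0 in the exact test at the site, which none of the 4 had the fragments to pass. The TSS share moved from 72.4% to 77.6% for promoters within 1 kb, 75.5% at a q of 0.01, 92.0% with a pileup of at least 20 and 69.2% in the exact test with the caller's window. Naive and memory T cell genes passed the threshold at a q of 0.01 (40%, adjusted p = 0.0395) and in the exact test with the caller's window (35%, adjusted p = 0.0412), with adjusted p up to 0.393 under the others, and the cause was not tested. The shares of the other 12 lists stayed on their side of the threshold under all 4 alternatives run for them, and no direction of a called list turned. Among lists that were not called, some shares moved by over 1.5 times. With 5 kb flanks, regulatory T cell genes went to 52.6%, myeloid markers to 35%, B cell markers to 6.25% and CD8 T and NK cell markers to 8.33%. With promoter peaks alone, regulatory T cell genes went to 15.8% and Th2 and Th17 genes to 16.7%, and at a q of 0.01 regulatory T cell genes went to 15.8% and Th1 and cytotoxic effector genes to 13.9%. In the exact test with the caller's window, Tfh genes (54.3%) lay above AP-1 and NF-κB genes (52.2%). No paired analysis was possible because no column carries a sample or a replicate number. For the same reason leaving out each replicate, other normalizations, filters on counts, pseudocounts, DESeq2, an unadjusted p, a q of 0.1 and an estimated correlation were not run, and the motif alternatives needed a genome sequence. Depth on the control side also limits the exact test at the site, which needs 39 anti-IFNAR1 fragments to reach the largest p of the list where the control side has 0.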

Other observations

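All tests here were chosen after the data were seen, and those of gene families and of explanations after the results they measure, except the exact test over the whole list, which was chosen before its own result was seen. Of 15 gene families taken by symbol, none of the 1110 olfactory receptor genes had a listed peak, and 1 of 355 vomeronasal receptor genes and 1 of 112 keratin genes had one (Fisher's exact test against other protein-coding genes, adjusted p = 1.60e-116, 2.30e-34 and 6.53e-10). C-type lectin NK receptor genes had 0 of 29 (adjusted p = 0.00615). Cytosolic ribosomal protein genes were listed in 40 of 101 cases (39.6%, adjusted p = 8.22e-05) and translation initiation factor genes in 21 of 56 (37.5%, adjusted p = 0.0117). Lysine demethylase genes, the family of Kdm3b, had 8 of 18 (44.4%, adjusted p = 0.0773), and proteasome subunits 13 of 40 (32.5%, adjusted p = 0.122). Mitochondrial ribosomal protein genes were listed in 20 of 78 cases (25.6%) and complex I genes in 12 of 49 (24.5%), near the 21.0% of other genes. The median fold was 5.19 on chromosome X and lay between 4.48 and 4.92 on the autosomes, a difference that was not tested.

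The list was concentrated at promoters, those of housekeeping genes included. Sites closed on the control side were argued against for the peaks whose background was counted at the site as a group, which made up 37.2% of the list and at most 13.6% in 1000 simulations at the genome rate. Closure stays open for the 31.6% with 0 control fragments at the site. It also stays open for the other peaks with a background from a window, whose control fragments at the site are unknown. Sampling noise of the shallower control side stays open. The exact test at the site kept at least 1335 peaks, where chance would give 547 if each 236 bp site of the caller's built-in mouse genome size was tested once. That number leaves out that each peak is taken at its summit, the highest of many overlapping positions, so the comparison does not decide. The bound of 50% set for the exact test with the caller's window decided nothing. That test kept 68.7% of the list, but all 4016 peaks with a wider window or the genome rate were among those kept. It counts unscaled fragments, where the caller used scaled-down coverage, and it uses the wider window. These effects were not separated, so the share does not speak to noise. In parts of the list the test also has little power. It called 21.0% of simulated 5-fold peaks with control fragments counted at every site, and wider windows were not simulated. Of the peaks with the background counted at the site 15.8% were kept. Of the others at least 23.9% were kept in the test at the site, which 45.3% of them could have reached with 0 control fragments. A higher signal over background in the anti-IFNAR1 libraries at open promoters in general and a broad opening of active promoters by the antibody cannot be told apart, since the 62.5% of housekeeping genes listed is part of the pattern itself and 0 columns hold values of single mice.

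The Il21 and Ifng peaks are a hypothesis of gained accessibility that these data leave open. In the exact test with the caller's window 1 of the 4 locus peaks was kept, but fragment number and window fixed that outcome, since none had the 39 fragments the test at the site needs and every peak with a wider window was kept. Sampling noise of the shallower control side therefore cannot be told apart from a gain at these loci at this depth. The general excess at promoters applies to the Il21 peak as well, and a gain particular to these cytokine genes was not tested.

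The Mpp7 peak may reflect a local gain or extra copies of the sequence on the anti-IFNAR1 side. Multi-copy sequence present in every mouse was argued against, since the control background there was 0.425 fragments, below the median of 1.49. The peak was picked for its small q, which favours a low background, so the median is a weak yardstick. Such sequence would raise the control side too, which stood at 0.425 against 170 fragments on the 3.54 times deeper anti-IFNAR1 side. A peak from 1 library of the anti-IFNAR1 pool was not tested, and needs values per mouse.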
